A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

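RNA was measured in 5 Saccharomyces cerevisiae strains of the BY4741 background, with 2 biological replicates per strain and 10 libraries in all, per the labels. Cells were grown in YPD at 30 °C and harvested in mid-log phase. Total RNA was purified with a MasterPure yeast kit and libraries were made from 8 µg with the Illumina TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols, and the platform was a HiSeq2000. The deposited values are 1 table with 1 column per strain, so the replicates appear only as a combined value, and how they were combined is not given in the sources used here. The table's header names no unit. The values were taken as the authors' FPKM, which are scaled to transcript length and library size, because they are decimals, the columns sum to between 2056298 and 2426410, above what CPM or TPM allow, and the highest values belong to very short features. The submitters' processing notes name FastQC, TopHat2 2.0.5, Cufflinks 2.0.2, Cuffdiff and R 2.15.1, with no role or order. The scaling between strains, the genome build and the annotation are not given in the sources used here. The table had 0 columns that were not used.

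Depth is unknown. The low values gave no steps of whole reads to read it from, since only 2 features were above 0 in every strain and below 0.3 FPKM in all of them. With 1 value per strain there is no estimate of the spread between replicates, so no test, interval or p-value is given, and every ratio describes these strain values alone. An exact 0 can be a failed estimate in such a table. In all, 117 features were listed at 0 in at least 1 strain, among them TEF1 and TEF2, the abundant genes of translation elongation factor 1A, in the double deletion. Such features are said only to be listed at 0.

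Ratios were computed as log2((FPKM + 1) / (reference FPKM + 1)), which understates the difference of scarce transcripts, over the 6541 of 6663 features with a mean of at least 1 FPKM. The 8 comparisons were each mutant against the wild type, the double deletion against each single deletion, SET5 Y402A against set5Δ, and the interaction, the double deletion minus the sum of the single deletions relative to the wild type. Features at least 2-fold higher and lower were counted. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined, in a form that covered tables of counts, of values per library and of 1 value per strain, and the last form was applied.

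Names, gene order along chromosomes, coding length and the share of 50-base sequences found once in the genome were taken from the RefSeq annotation of assembly R64, which may not be the annotation behind the table, so no coordinates are given. Among the genes named in the text, BNA2, DIA1, YMR316C-A, MET17, PHO84 and SNR18 overlap another annotated gene, and FIT1, FLO1, HSP82, MF(ALPHA)1, PAU9, PHO5, TPO2, YPS6, TEF1, TEF2, the Ty open reading frames and the YRF1 genes and most COS genes other than COS12 share sequence with other genes, so their values are less certain. Whether reads of the active mating locus, MATa in these strains, are counted in the silent mating cassettes, HMRA1 among them, was not tested. Of the features, 5934 were matched by locus tag, 82 by symbol and 647 not at all. For each of 36 gene lists, the median log2 ratio was set beside the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these strain values. The random lists could include the list's own members, which matters most for large lists. A list is called outside the matched range when its median lay below percentile 2.5 or above percentile 97.5. Subtelomeric genes were the outermost 10 annotated genes at each chromosome end. The subtelomeric and retrotransposon lists were chosen with knowledge of the published study's title. The mitochondrially encoded list had 0 of 22 members in the table, and of the 4 genes deleted in the strain background only HIS3 had a mean of at least 1 FPKM, so neither list has a median.

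Named genes were SET1 and SET5, then per comparison the 10 highest and 10 lowest log2 ratios among features with at least 10 FPKM in the higher strain, up to 4 members per list with the largest ratio, and a set of single genes. Ty open reading frames, genes deleted in the background, and SET1 and SET5 took no places. Many features picked this way were short or absent from the annotation. A ranking of coding genes of at least 300 bp, at least 10 FPKM and above 0 in the strains compared was therefore added after the values were seen, and other genes were named after their values were seen.

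The counting was tested on simulated data, in which both columns were built on the 6541 wild-type values, with 200 changed genes. The changed genes were drawn from those of at least 10 FPKM in the wild type, so recovery of scarcer features was not simulated. A 3-fold difference was recovered in 100.0% of changed genes at a noise of 0.1 (SD, log2), and in 88.0% at a noise of 0.3. At a noise of 0.3, 1.59% of unchanged genes were also counted. At these noise levels 0.5% and 15.5% of genes with a 1.5-fold difference were counted. Of 100 unchanged lists, 5 fell outside the range that should hold 95% of them. Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 10 FPKM, median centring, quantile normalization, thresholds of 1.5-fold and 3-fold, leaving out Ty open reading frames, and subtelomeric lists of the outermost 5 or 20 genes. The coding-gene restriction, leaving out features listed at 0, the subtelomeric genes of unique sequence and quantile normalization for the lists were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.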

Results

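Polyadenylated RNA was profiled by sequencing in 5 strains of the haploid budding yeast BY4741. They were the wild type, a strain without SET1, a strain without SET5, a strain without both genes, and a strain in which Set5 carries the substitution Y402A. Set1 is the methyltransferase of histone H3 lysine 4 and Set5 is a methyltransferase of histone H4. All strains grew in rich glucose medium at 30 °C to mid-log phase. The labels describe 2 biological replicates per strain, 10 libraries in all, while the table gives 1 FPKM per gene and strain. No difference below therefore has a replicate check, no test was run, and the sequencing depth is unknown. The table holds 6663 features, of which 6541 had a mean of at least 1 FPKM over the strains and were compared. The sum of FPKM was 2368910 in the wild type, 2199480 in set1Δ, 2426410 in set5Δ, 2056298 in set1Δ set5Δ and 2362791 in SET5 Y402A.

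The targeted genes followed the strain labels. SET1 (YHR119W) stood at 24.3 FPKM in the wild type, 24.2 in set5Δ and 25.6 in SET5 Y402A, against 0.0328 in set1Δ and 0.0324 in set1Δ set5Δ. SET5 (YHR207C) stood at 34.6 FPKM in the wild type, 37.8 in set1Δ and 41.8 in SET5 Y402A, against 0.0545 in set5Δ and 0.0167 in set1Δ set5Δ. The substitution strain thus carried SET5 transcript at a level close to that of the wild type.

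**Figure D1:**
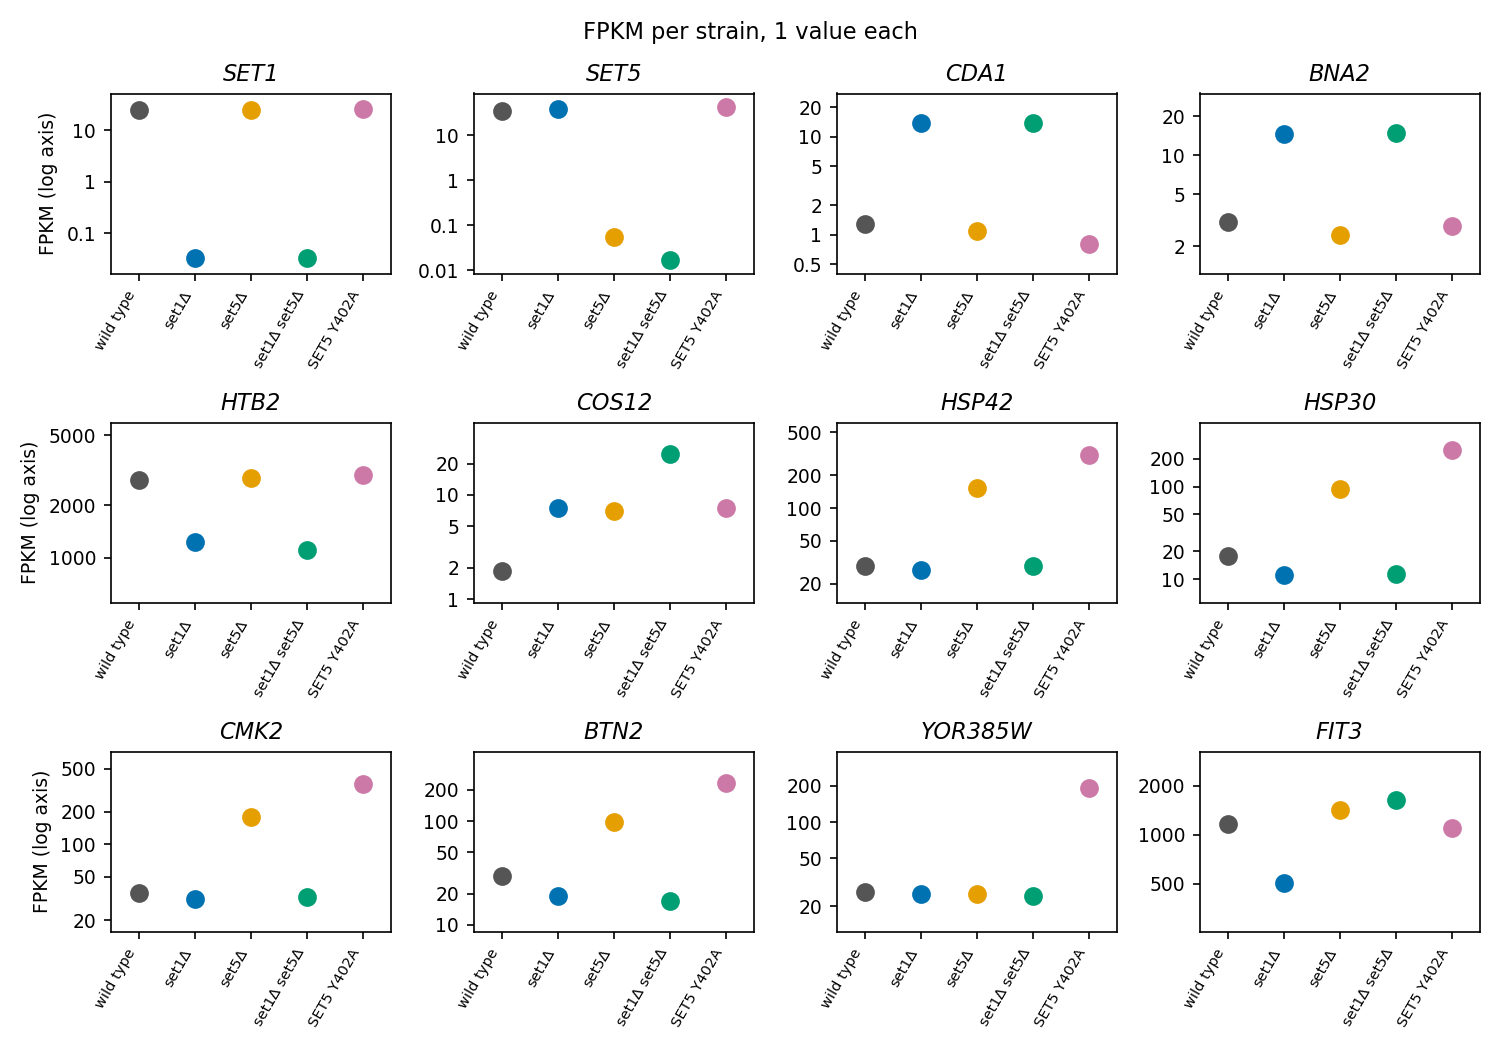
FPKM (log axis, scaled separately in each panel) of 12 genes in the 5 strains, 1 point per strain and no error because the table has 1 value each. CDA1 and BNA2 were high and HTB2 was low in both strains without SET1, and HSP42, HSP30, CMK2 and BTN2 were high in set5Δ and SET5 Y402A.

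The first comparison asked which transcripts differ when SET1 is absent. Several metabolic and sporulation genes were higher in set1Δ than in the wild type. CDA1, a chitin deacetylase of the spore wall, stood at 13.8 against 1.29 FPKM, BNA2, which opens the kynurenine route to NAD, at 14.7 against 3.05, and MUP3, a methionine permease, at 13.3 against 2.01. MIG2, a repressor of glucose-repressed genes, was at 152 against 58.4 FPKM, the replication licensing gene CDC6 at 26.4 against 9.65, and MDH2, cytosolic malate dehydrogenase, at 179 against 78.0. The histone genes were lower, with HTB2 (histone H2B) at 1224 against 2769 FPKM and HTA2 (histone H2A) at 1056 against 1998. The glucose transporter gene HXT2 was also lower, at 440.3 against 877 FPKM, as was FIT3, a cell wall protein that retains siderophore iron, at 505 against 1169.

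In all, 155 features were at least 2-fold higher and 32 at least 2-fold lower in set1Δ, on the scale of log2(FPKM + 1). With quantile-normalized values the split was 102 to 58. Among the 187 features past 2-fold, 58 were shorter than 300 bp, 41 had no length in the annotation used, 81 were below 10 FPKM and 32 were listed at 0 in a compared strain, which gives them no interpretable fold. Coding genes of at least 300 bp, at least 10 FPKM and above 0 in both strains numbered 31 higher and 7 lower, a restriction chosen after the values were seen. By the rule fixed in advance the highest feature was SNR18 (3.26), and 8 of the 10 highest and 7 of the 10 lowest were shorter than 300 bp or absent from the annotation, so the longer coding genes named here come mostly from a ranking made after the values were seen.

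Gene groups differed from random groups of matched expression in both directions in set1Δ. All 10 histone genes were lower, with a median log2 ratio of -0.59, below every one of 10000 random lists. All 12 genes of the G2/M list, such as the mitotic cyclin gene CLB2 (0.52) and the transcription factor gene SWI5 (0.47), were higher, with a median of 0.42, and none reached 2-fold. The middle sporulation genes had a median of 0.62, with 23 of 30 measured members higher and 7 at least 2-fold higher, CDA1 (2.69), LOH1 (1.51) and DIT1 (1.33) among them. Most of that list was scarce, and its median was -0.12 over members with a mean of at least 10 FPKM. The seripauperin genes, a family of near-identical cell wall proteins, had a median of 0.62 over 17 members and the anaerobic mannoprotein genes one of 0.41 over 6. With quantile-normalized values these 3 medians shrank to 0.13, 0.33 and 0.16. The arginine list had a median of 0.35, with ARG3 at 0.90 and ARG1 at 0.72, purine synthesis one of 0.14, respiration one of 0.20 over 44 genes, and stress-induced genes one of 0.19 over 43. The iron regulon had a median of -0.17. Ribosome biogenesis stood at 0.04. Ribosomal RNA features had a median of 0.84 in this strain. Whether this was carry-over into a library of polyadenylated RNA was not tested.

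The second comparison asked which transcripts differ when SET5 alone is absent. Several stress genes were higher in set5Δ. HSP42, a small heat-shock chaperone, stood at 153 against 29.0 FPKM, HSP30, a plasma membrane stress protein, at 93.5 against 17.9, CMK2, a calmodulin-dependent kinase, at 181 against 35.7, and BTN2, which acts on misfolded proteins, at 98.4 against 29.3. DIA1 was at 80.7 against 17.5 FPKM, but it overlaps YMR316C-A, and reads from overlapping genes cannot be separated without strand. On the low side, PAU9 stood at 3.21 against 31.2 FPKM, a value that is uncertain because the gene shares its sequence with other seripauperin genes, and SIR2, the silencing deacetylase, at 16.2 against 31.4. In total 65 features were at least 2-fold higher and 38 lower. Under the coding-gene restriction described above, 22 were higher and 0 lower.

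Among the groups, the stress-induced list had a median log2 ratio of 0.22 in set5Δ, above all random lists, with 37 of 43 members higher and 2 at least 2-fold higher. Ribosome biogenesis genes went the other way, with 94 of 101 lower and a median of -0.10, below all random lists. Histone genes had a median of 0.14, the M/G1 list 0.16, and the COS family, membrane proteins encoded near chromosome ends, 0.15. Small medians below the matched range were found for pheromone response genes (-0.12), methionine and sulfate assimilation (-0.09), purine synthesis (-0.08) and the PHO regulon (-0.08). Those of G1/S genes (-0.08) and middle sporulation genes (-0.13) lay below it too. Small nucleolar RNAs had a median of -0.22, also below the range, but a mean of 0.05. Of these 52 features, 6 were at least 2-fold higher, 5 were lower and 6 were listed at 0 in a compared strain. Ribosomal RNA had a median of -0.02, although 4 of its 14 features, all copies of 5S ribosomal RNA, were at least 2-fold higher.

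The third comparison asked how the strain with altered Set5 differs from the wild type. HSP30 at 245 FPKM, HSP42 at 308, CMK2 at 360.3 and BTN2 at 234 stood further from the wild type than in set5Δ, and PAU9 at 23.8 and SIR2 at 27.3 stood closer to it. The chaperone genes HSP104 (257 against 71.7 FPKM) and HSP82 (367 against 113) were higher as well, as were the polyamine exporter genes TPO2 (144 against 22.7) and TPO4 (58.2 against 11.6). YOR385W was at 192 against 26.3 FPKM and stayed between 24.6 and 26.3 in the other strains. In total 120 features were at least 2-fold higher and 21 lower, of which 63 and 1 under the coding-gene restriction. The single lower coding gene was YGR079W (-1.02), named after its value was seen.

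The stress-induced list had a median log2 ratio of 0.47 in SET5 Y402A, with 39 of 43 members higher and 9 at least 2-fold higher, HSP104 (1.83) and SPI1 (1.94) among them. Of other stress genes, HSP12, a membrane stress protein gene, stood at 0.83 and SSA3, an Hsp70 gene, at 0.09. Ribosome biogenesis genes had a median of -0.19, with 98 of 101 lower. The COS family had a median of 0.36 with 11 of 11 members higher, although most share sequence and are not 11 separate measurements. Histone genes had a median of 0.25, respiration 0.09 and the M/G1 list 0.11. Lists below the matched range were arginine metabolism (-0.15), the iron regulon (-0.14), pheromone response genes (-0.14), the PHO regulon (-0.14), methionine and sulfate assimilation (-0.10) and middle sporulation genes (-0.10). Ribosomal RNA features had a median of 0.94, and the cause was not tested.

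Against set5Δ directly, SET5 Y402A had 54 features at least 2-fold higher and 21 lower, of which 13 and 0 under the coding-gene restriction. YOR385W (2.88), TPO4 (1.47), HSP30 (1.38), BTN2 (1.24) and HSP104 (1.11) were among the higher coding genes. The stress-induced list had a median of 0.25 with 38 of 43 members higher, and ribosome biogenesis one of -0.09. In coding genes measurable in both comparisons, 22 of 5052 were at least 2-fold higher in set5Δ than in the wild type, 59 in SET5 Y402A, and 22 in both. Independent lists of these sizes would share 0.257 genes, and the highest overlap in 100 simulations of unchanged strains against a shared wild type was 0. The table gives no replicates, so the noise was assumed from the spread of set5Δ ratios across genes. At that noise almost no unchanged gene can reach 2-fold, so the 0 says nothing about the shared wild type. Both comparisons use the same wild-type values, so part of the overlap may come from them. With set1Δ as the reference for set5Δ, which removes the shared column, 37 genes were higher and 22 of them were also higher in SET5 Y402A against the wild type, where independent lists would share 0.432.

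The double deletion was compared with the wild type to ask what is seen when both enzymes are missing. Several coding genes that were high in set1Δ were high here too, with CDA1 at 13.9 FPKM, MUP3 at 15.4, MIG2 at 179 and MDH2 at 203. The histone genes were low, with HTB2 at 1109 and HTA2 at 891. COS12, a member of a subtelomeric gene family, stood at 24.7 FPKM against 1.86 in the wild type, 7.53 in set1Δ and 7.06 in set5Δ. QDR2, a drug exporter gene, was lower at 35.0 against 83.0 FPKM, and so was PRP11, a splicing factor gene, at 22.1 against 49.0. Of the genes named as high in set5Δ, HSP42 at 29.0 and CMK2 at 32.7 FPKM stood near the wild type, and HSP30 at 11.4 and BTN2 at 17.2 stood below it, close to their levels of 11.2 and 19.0 in set1Δ. In total 185 features were at least 2-fold higher and 34 lower, and with quantile-normalized values the split was 119 to 60. Under the coding-gene restriction 52 were higher and 9 lower.

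Genes near chromosome ends and retrotransposon genes were examined as groups in the double deletion. Both lists were chosen with the title of the published study of these strains in mind, so they are not independent of these samples. The outermost 10 genes at each chromosome end (295 measured) had a median log2 ratio of 0.22 to the wild type, above all random lists, with 34 at least 2-fold higher and 0 lower. That median shrank to 0.07 with quantile-normalized values and was also 0.07 over members with a mean of at least 10 FPKM. In set1Δ alone 22 were at least 2-fold higher and 1 lower. The same list had medians of 0.07 in set1Δ, 0.01 in set5Δ and 0.02 in SET5 Y402A, and the sign of each of these 3 was reversed with quantile-normalized values. By position, the median in the double deletion was 0.32 over genes 1 to 5 from the end, 0.14 over genes 6 to 10, 0.04 over genes 11 to 20 and -0.00 over genes 21 to 40. Many of these genes have near-identical copies, and over the 151 whose 50-base sequences were at least 95% unique the median was 0.10, at percentile 80.9 of random lists of such genes. PHO89, a phosphate transporter gene, FIT1, COS12 and YPS6 were among the 7 subtelomeric genes of the 52 higher coding genes.

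**Figure D2:**
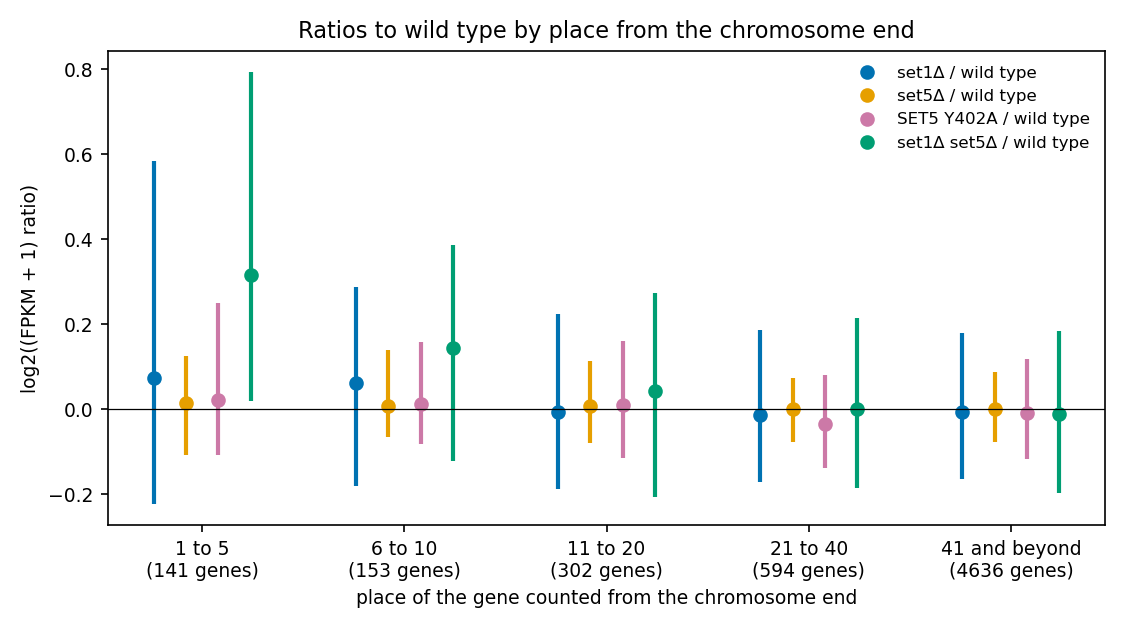
Median log2 ratio of FPKM + 1 to the wild type (points) with the lower and upper quartile over genes (lines), for genes grouped by their place from the chromosome end, in the 4 mutant strains. The double deletion had a median of 0.32 over the outermost 5 genes and stayed near 0 beyond gene 20.

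Ty open reading frames, the genes of the yeast retrotransposons, had a median FPKM of 58.0 in the wild type, 65.1 in set1Δ, 62.9 in set5Δ, 66.8 in SET5 Y402A and 77.1 in the double deletion. Their median log2 ratio to the wild type was 0.46 in the double deletion, 0.15 in set1Δ, 0.03 in set5Δ and 0.10 in SET5 Y402A. In the double deletion 48 of 52 were higher and 0 passed 2-fold. Of the 53 in the table, 50 had a known share of unique sequence, and all 50 were under 95% unique. Single elements therefore cannot be told from their copies.

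Other groups in the double deletion followed those of set1Δ or stood apart from them. Histone genes had a median of -0.73, G2/M genes 0.41 with 12 of 12 higher, middle sporulation genes 0.56, seripauperins 0.68, anaerobic mannoproteins 0.59, arginine metabolism 0.61 and purine synthesis 0.10. With quantile-normalized values the medians of middle sporulation genes, seripauperins and mannoproteins shrank to 0.07, 0.45 and 0.25, and the first was -0.10 over members with a mean of at least 10 FPKM. Ribosome biogenesis genes stood at 0.06. Cytosolic ribosomal protein genes had a median of -0.30, with 133 of 135 lower, against -0.12 in set1Δ, -0.01 in set5Δ and -0.06 in SET5 Y402A. The matched range in the double deletion was -0.29 to -0.25, and in set1Δ the value lay inside the matched range. Random lists could draw these same 135 genes, which pulls the range toward their own median. That range therefore cannot tell what was particular to them. The value of the double deletion was -0.31 after median centring and shrank to -0.02 with quantile-normalized values. Quantile normalization can remove a shift shared by the most abundant genes. The iron regulon stood at 0.16, above the matched range, and the YRF1 helicases at 0.27, inside it. Stress-induced genes stood at 0.14, inside the matched range, and respiration at 0.00, above it but of no clear direction. Ribosomal RNA stood at 0.57.

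**Figure D3:**
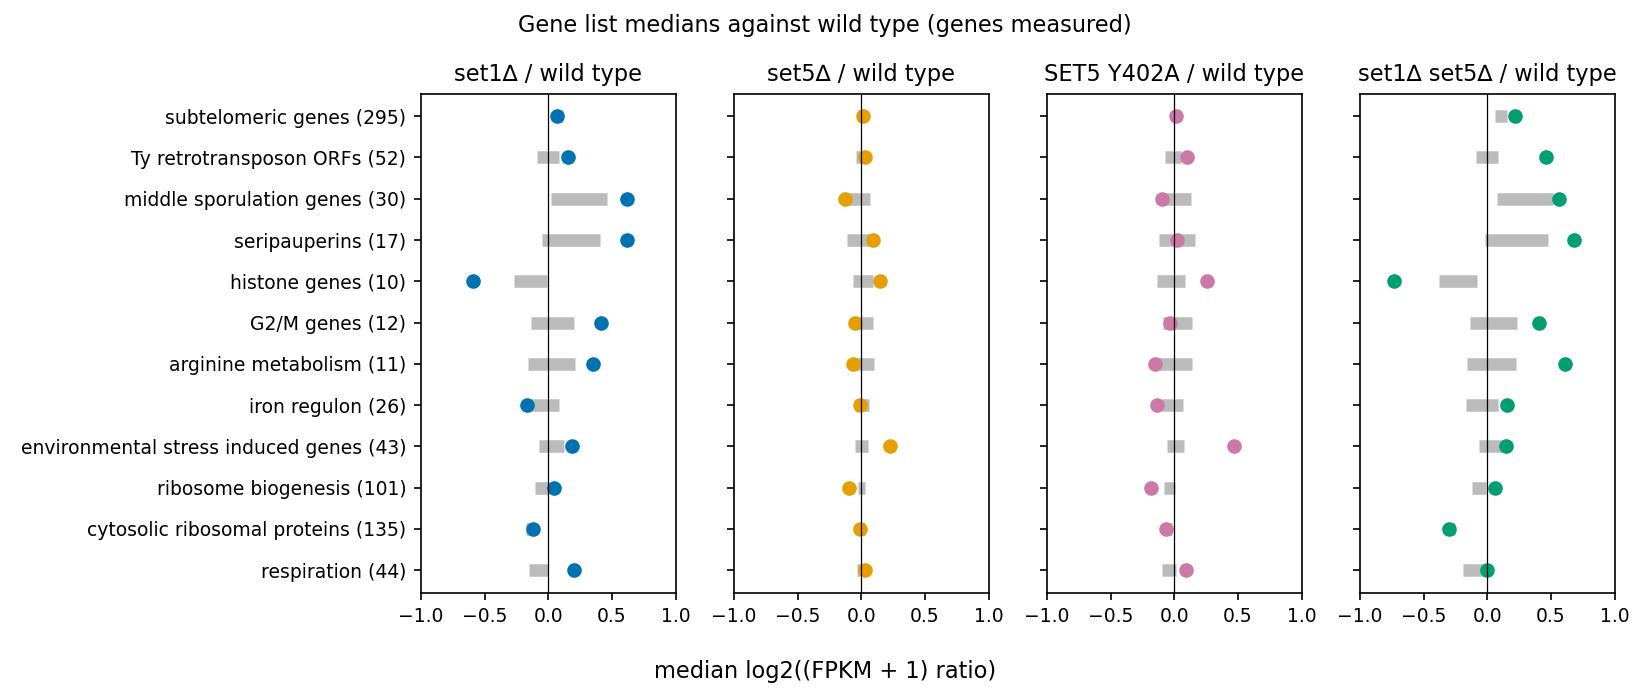
Median log2 ratio to the wild type of selected gene lists in the 4 mutant strains (points), over grey bars that span the range holding 95% of 10000 random lists of matched expression. Numbers in brackets are the genes measured; histone genes lay below the bars in both strains without SET1, and stress-induced genes lay above them in set1Δ, set5Δ and SET5 Y402A.

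Setting the double deletion against set1Δ isolates the absence of SET5 in a strain that already lacks SET1. Genes of iron uptake were higher in the double deletion. FIT3 had a log2 ratio of 1.68 to its level of 505 FPKM in set1Δ, while FIT2 stood at 2266 against 872 FPKM, FIT1 at 58.0 against 22.7 and ARN2, a siderophore transporter gene, at 199 against 96.9. FIT3 and FIT2 did not differ to that extent from the wild type, where they stood at 1169 and 1368 FPKM. In total 37 features were at least 2-fold higher and 23 lower. Under the coding-gene restriction 5 were higher, these 4 and COS12, and 0 were lower. FIT1, ARN2 and COS12 are also in the subtelomeric list, so the iron and subtelomeric groups share members.

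As groups, the iron regulon had a median of 0.35 in the double deletion over set1Δ, with 25 of 26 members higher, 4 of them at least 2-fold, and HMX1, the heme oxygenase gene, at 0.70. The YRF1 helicase genes of the subtelomeric repeats had a median of 0.32, with 8 of 8 higher, although these copies are nearly identical and are not 8 separate measurements. The COS family stood at 0.29, Ty open reading frames at 0.29, subtelomeric genes at 0.13, seripauperins at 0.23 and arginine metabolism at 0.11. Over the 151 subtelomeric genes with unique sequence the median was 0.06, above all random lists of such genes. Cytosolic ribosomal protein genes had a median of -0.19, with 134 of 135 lower, beside a matched range of -0.15 to -0.11 that could draw on these same genes. That median was -0.20 after median centring and shrank to -0.02 with quantile-normalized values. Respiration had one of -0.17, with 40 of 44 lower, and silent mating cassettes one of -0.19 over 3. Ribosomal RNA features stood at -0.61, lower in the double deletion.

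Against set5Δ, the double deletion, which lacks SET1 as well, had 187 features at least 2-fold higher and 70 lower. The split was 112 to 94 with quantile-normalized values. Under the coding-gene restriction 44 were higher and 39 lower. CDA1 (2.83), BNA2 (2.21), LOH1 (1.78) and CDC6 (1.57) were among the higher genes. The lower genes included HSP30 (-2.93), BTN2 (-2.45), CMK2 (-2.43) and HSP42 (-2.36), and HAP4, a regulator of respiration genes, stood at -1.67. Histone genes had a median of -0.94, G2/M genes 0.46, subtelomeric genes 0.22, Ty open reading frames 0.44 and ribosome biogenesis 0.14. The subtelomeric median shrank to 0.06 with quantile-normalized values.

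The interaction compared the double deletion with the sum of the single deletions on the log2 scale. FIT3 (1.41) and FIT2 (1.06) were above that sum, and HSP30 (-2.30), HSP42 (-2.25), CMK2 (-2.24) and BTN2 (-1.85) were below it. A total of 51 features lay at least 2-fold above and 80 at least 2-fold below, of which 2 and 24 under the coding-gene restriction. The iron regulon had a median of 0.33, Ty open reading frames 0.29, YRF1 helicases 0.39, subtelomeric genes 0.12 and ribosome biogenesis 0.13. Over the 151 subtelomeric genes with unique sequence the median was 0.03, at percentile 74.3 of random lists of such genes. Stress-induced genes had a median of -0.19, respiration -0.23 and ribosomal RNA -1.27. The median of the ribosomal protein genes, -0.18, was -0.19 after median centring and became 0.02 with quantile-normalized values. Its direction thus depends on the scaling. Because quantile normalization can remove a shift shared by the most abundant genes, the 0.02 does not settle it.

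Of the 34 lists with a median, 13 lay outside the matched range in set1Δ (11 with a median above 0), 13 in set5Δ (4 above 0), 14 in SET5 Y402A (7 above 0) and 14 in the double deletion (12 above 0). Some lists stayed inside it against the wild type in all 4 mutants, the YRF1 helicases among them at -0.05, -0.07, -0.03 and 0.27. Median log2 ratios in set1Δ, set5Δ, SET5 Y402A and the double deletion were 0.05, -0.02, -0.05 and 0.05 for silencing factors and -0.00, -0.07, -0.05 and -0.01 for other members of the Set1 complex. For the silent mating cassettes they were 0.10, 0.08, 0.11 and -0.07, for alpha-specific genes 0.41, -0.07, -0.10 and 0.41, and for a-specific genes -0.06, -0.01, -0.11 and -0.22. Ergosterol synthesis gave -0.16, -0.00, -0.10 and -0.09, NAD synthesis -0.10, -0.05, -0.01 and -0.11, and flocculins -0.01, 0.06, 0.15 and 0.15. NAD synthesis held BNA2, and its mean in set1Δ was 0.25 although its median was below 0. Maltose genes gave 0.06, -0.05, -0.03 and 0.10, galactose genes 0.16, -0.02, -0.05 and 0.26, and hexose transporters -0.00, 0.02, -0.07 and 0.14. With quantile-normalized values the medians of silencing factors, maltose genes and galactose genes were below 0 in both set1Δ and the double deletion, and those of flocculins and hexose transporters in the double deletion. That of the hexose transporters in set5Δ also turned below 0, and NAD synthesis in SET5 Y402A turned above 0 after median centring.

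Single genes were also followed. PHO84, the high-affinity phosphate transporter gene, stood at 1198 FPKM in the wild type, 1428 in set1Δ, 1069 in set5Δ, 824 in SET5 Y402A and 1401 in the double deletion, and PHO5, an acid phosphatase gene, at 130.1, 242, 114, 104 and 156. ERG11, of ergosterol synthesis, stood between 496 and 577 FPKM and HMRA1, annotated at the silent mating locus, between 132 and 149. Whether the HMRA1 reads came from that locus or from the active mating locus was not tested. The log2 ratios of HSP12 were 0.95 in set1Δ and 1.42 in the double deletion, those of STE3 0.68 and 0.59 and those of MF(ALPHA)1 1.82 and 2.17. HIS3, a gene deleted in this strain background, had ratios of 0.65 and 0.63 in these strains, and the source of its reads was not tested. SPS2 and FLO1 had ratios of -0.05 and -0.01 in set1Δ. LEU2 and MET17, also deleted in this strain background, had ratios of -0.14 and 0.03 in set1Δ at levels below 1 FPKM.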

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

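In this part, the tests of SET5 loss whatever the state of SET1, of growth state, of combined loss, of shared reads as the whole cause of the difference from set1Δ, and of failed estimates were chosen after the results were seen.

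The absence of SET5 went with medians of opposite sign for ribosome biogenesis genes in strains with and without SET1. Their median log2 ratio was 0.0296 for the double deletion over set1Δ and -0.0964 for set5Δ over the wild type. With 1 value per strain this difference was not tested.

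The stress genes HSP42, HSP30, CMK2 and BTN2 were high in set5Δ and SET5 Y402A and not in the double deletion. There HSP42 and CMK2 stood near the wild type and HSP30 and BTN2 below it. Not every stress gene followed them, and HSP12 was higher in the double deletion and in set1Δ than in the wild type. The stress-induced list as a whole differed less between strains than these genes. Its medians were 0.4656 in SET5 Y402A, 0.2219 in set5Δ, 0.1887 in set1Δ and 0.1431 in the double deletion. Of its 43 members, 9 were at least 2-fold higher in SET5 Y402A, 2 in set5Δ, 1 in set1Δ and 2 in the double deletion. Short transcripts are argued against, since the stress-induced list lay at percentile 100 of random lists matched on expression and length in set5Δ and SET5 Y402A. A loss of SET5 that acts whatever the state of SET1 is argued against as well. In the 22 genes at least 2-fold higher in set5Δ and SET5 Y402A, the median log2 ratio of the double deletion over set1Δ was 0.0424. Those 2 columns were not used to choose the genes. The stress-induced list, which was not chosen from these values, had a median of 0.0175, inside the matched range. A difference in growth state between cultures may be the cause. Ribosome biogenesis genes were low in set5Δ and SET5 Y402A, with a median of -0.186 in the latter, as in a general stress state. Cytosolic ribosomal protein genes differed less, with medians of -0.0116 in set5Δ, below the matched range, and -0.0639 in SET5 Y402A, inside it. Those ranges could draw on these same genes. The ribosomal protein genes add little to this reading. An action of Set5 that needs SET1 also stays open, and with no separate values for the cultures it was not tested against growth state.

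Subtelomeric genes were higher in the double deletion. Low expression or short length as the whole cause is argued against, since the list lay at percentile 99.97 of random lists matched on both. Reads shared between repeated genes stay open for the difference from the wild type, where the 151 genes of unique sequence lay at percentile 80.94 of such genes. Uniqueness was not separated from place, and the median fell from 0.315 over genes 1 to 5 to 0.1433 over genes 6 to 10. That percentile therefore cannot decide. Shared reads do not account for the whole difference from set1Δ, where those 151 genes lay at percentile 100 with a median of only 0.06. A combined effect of losing SET1 and SET5 cannot be told apart from reads shared between repeated genes. The interaction had a median of 0.1227, at percentile 100 over the whole list and 74.3 over the genes of unique sequence. Here too, uniqueness was not separated from place.

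In 19 features a strain was listed at 0 while another stood at 100 FPKM or more, 7 of them in the double deletion. Over all features the double deletion had the fewest listed at 0, 20. There were 76 in the wild type, 21 in set1Δ, 68 in set5Δ and 56 in SET5 Y402A. TEF1 and TEF2, a pair with near-identical sequence, stood at 12059 and 12637 FPKM in the wild type and were listed at 0 in the double deletion alone. Failed estimates for short or repeated features are a candidate explanation that stays open. Of those with a known length 100% were short or repeated, but a length was known for only 73.7% of the 19, so that check is void, and no biological explanation was tested.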

How the results depend on the processing

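The coding-gene restriction, leaving out features listed at 0, the subtelomeric genes of unique sequence and quantile normalization of the lists were alternatives chosen after the data were seen. Counts are features at least 2-fold different in either direction, in the order set1Δ, set5Δ, SET5 Y402A and the double deletion against the wild type, the double deletion against set1Δ and against set5Δ, SET5 Y402A against set5Δ, and the interaction. All 8 counts stayed within 1.5 times those of the report with a pseudocount of 0.1, without the filter, after median centring, with quantile normalization, without Ty open reading frames and without features listed at 0. Other thresholds moved every count by construction. They were 604, 255, 353, 728, 122, 788, 201 and 339 at 1.5-fold, and 72, 47, 61, 84, 31, 86, 33 and 66 at 3-fold. Fewer features could pass under the coding-gene restriction, with 38, 22, 64, 61, 5, 83, 13 and 26. A pseudocount of 5, which shrinks scarce transcripts, gave 79 in set1Δ, 103 in the double deletion, 129 against set5Δ and 47 for SET5 Y402A against set5Δ. A mean of at least 10 FPKM, which leaves fewer features, gave 88 in set1Δ, 109 in the double deletion, 38 against set1Δ and 130.0 against set5Δ. The subtelomeric median kept its sign in the double deletion under every alternative run. In the order against the wild type, set1Δ and set5Δ, and then the interaction, it was 0.1544, 0.0930, 0.1719 and 0.0969 with a pseudocount of 5, 0.0658, 0.1099, 0.0727 and 0.0939 at a mean of at least 10, 0.3150, 0.2457, 0.3794 and 0.2269 over the outermost 5 genes, 0.1185, 0.0580, 0.0946 and 0.0682 over the outermost 20, and 0.0995, 0.0645, 0.0921 and 0.0310 over genes of unique sequence. With quantile normalization it was 0.0711, 0.1045 and 0.0644 in the first 3. Against set1Δ it was 0.1464 with a pseudocount of 0.1, and against set5Δ 0.2506 without the filter. The Ty median against set1Δ was 0.2593 with a pseudocount of 5, and the other Ty medians involving the double deletion moved by less than 1 SD of the medians of random lists. At a mean of at least 10 FPKM the middle sporulation medians turned to -0.1156 in set1Δ, -0.0984 in the double deletion and -0.0153 against set5Δ, and the interaction of the seripauperins to 0.0285, and to 0.0149 without the filter, in each case over a different set of members. The interaction of the ribosomal protein genes turned to 0.0168 with quantile normalization and respiration in the double deletion to -0.0046 after median centring; the cause was not tested. Of 272 list medians, 92 moved with quantile normalization, 53 at a mean of at least 10, 26 with a pseudocount of 5, 10 with a pseudocount of 0.1, 5 without the filter and 1 after median centring. No paired analysis was possible because the table gives 1 value per strain, and for the same reason leaving out each replicate, the replicate block, other sets of libraries in the fit, other tests and an estimated gene set correlation were not run. Unknown depth limits scarce transcripts most.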

Other observations

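HUG1, a small inhibitor of ribonucleotide reductase, stood at 250.1 FPKM in the wild type, 1573 in set1Δ and 2554 in the double deletion, a value that is uncertain because the gene is shorter than 300 bp. RNR3, a damage-inducible ribonucleotide reductase gene, was at 3.90, 7.99 and 9.30 FPKM in these strains, RNR2 at 277, 363 and 458, and RNR4 at 659, 880.3 and 1075, whereas RNR1 was at 201, 164 and 192. In set5Δ these genes stood near the wild type, with HUG1 at 279 and RNR2 at 299 FPKM. These genes were named after their values were seen.

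SIR2 and its neighbour PRP11 were low in strains without SET5 or SET1. SIR2 stood at 31.4 FPKM in the wild type, 22.4 in set1Δ, 16.2 in set5Δ, 18.9 in the double deletion and 27.3 in SET5 Y402A, and PRP11 at 49.0, 33.4, 36.1, 22.1 and 49.4. NAT1, on the other side of SIR2, stood at 93.0, 78.0, 92.2, 75.3 and 93.4 FPKM. Genes beside the deletions were also listed. BAT1, next to SET5, stood at 718 FPKM in the wild type, 549 in set1Δ, 996 in set5Δ, 584 in the double deletion and 806 in SET5 Y402A.

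Strains could be compared pairwise over 5157 coding genes. In set1Δ and the double deletion, 13 genes were at least 2-fold above each of the other 3 strains and 2, HTB2 and ROQ1, were below them. In set5Δ and SET5 Y402A, 15 were above and 0 below, and each of the other 8 pairs of strains had 0 in either direction. In SET5 Y402A alone, 12 genes were at least 2-fold above the other 4 strains. These pairs were examined after the values were seen.

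The same deletion was also compared in separate columns. Across 5034 coding genes, which are not independent replicates, the log2 ratios of set1Δ to the wild type and of the double deletion to set5Δ had a Pearson r of 0.77 and a Spearman rho of 0.78, and of the 29 genes past 2-fold in the first, 28 had the same sign and 16 passed 2-fold in the second. For the absence of SET5, the ratios of set5Δ to the wild type and of the double deletion to set1Δ had an r of 0.03 and a rho of -0.06, and of the 22 genes past 2-fold in the first, 15 had the same sign and 0 passed 2-fold in the second.

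Ratios also varied with the level of expression. Over the 1309 features with the lowest mean FPKM the median log2 ratio was 0.15 in set1Δ and 0.21 in the double deletion, and over the 1308 with the highest it was -0.10 and -0.17. In set5Δ it was -0.01 and 0.00, and in SET5 Y402A 0.04 and -0.05.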
